A study of Homo sapiens with 43 samples.

How the data were processed

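The labels describe 43 ChIP-seq samples of SUDHL5 and KARPAS422. Peak lists were used for 33 of them; the 10 input libraries have no list of their own. Per the labels' protocol, the antibodies were ab239364 and CST2316S against CDK9 (the titles give the second number, the protocol text a different order of its digits), ab5095 against Ser2P, ab5131 against Ser5P and 8WG16 against Pol II, and Drosophila chromatin was added to the CDK9 samples. No value scaled to that chromatin was used here. Per the submitters' processing notes, FastQC, Trim Galore, Bowtie2, SAMtools, Picard, MACS2, bedtools and deepTools were used with builds hg38 and dm6. Versions, the control library behind each call and any blacklist filter are not given in the sources used here. The file names call the CDK9 DMSO samples 0 h where the labels say 2 h, and the labels were followed.

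The deposited lists hold the authors' fold enrichment of each peak, a ratio over the background of its own list that is not scaled between lists. They also hold the authors' -log10 p and -log10 q of each peak, and the lowest -log10 q in any list was 1.301. Because fold and q depend on the depth of a list, they were used only to rank peaks within a list and to set a stricter threshold (-log10 q of at least 5). The lists held 286536 peaks, of which 25 on unplaced contigs were left out. Read totals are not in these files, so the depth per sample is unknown and no interval from counting was given.

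Groups were DMSO and 30 nM CDK-TCIP1 by cell line, target, antibody and time, giving 9 comparisons. Ser2P, Ser5P and Pol II have DMSO lists at 4 h only, so that the 2 h and 4 h comparisons share them and differ from DMSO also in time for the 2 h samples. Peaks of all lists of a target, antibody and line were merged when they overlapped by at least 1 bp, and a list held a region when it had a peak in it. Genes were the 20033 protein-coding genes of a RefSeq table of GRCh38, the same build as hg38. That table has no strand, so the planned window around the gene start was replaced by 1 kb either side of either gene end. Ser2P was counted over the gene and 2 kb on each side.

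List lengths, covered bases and the share of peaks at gene ends were compared with exact two-sided permutation tests on the group means (list length on the log2 scale). CDK9 sets were combined with labels permuted within each line and both SUDHL5 antibodies permuted together. Gained and lost counts have no test per region or gene; each was set beside the counts from every other split of the same lists. Lists of 249 genes in 15 groups were tested with Fisher's exact test, two-sided, among genes with no DMSO peak in the set and a peak in at least 1 list of the study, with Benjamini-Hochberg adjustment over 135 tests. Overlaps between sets, and polymerase gains of CDK9-gained genes, used the same test, the second adjusted over 6 tests. Genes are not independent replicates in these tests, and neighbouring genes can share a peak.

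Named genes followed a rule: 15 fixed genes, the 10 gained genes with the best mean rank by q within the treated lists of each CDK9 set and over all 3 sets, the 5 gained and 5 lost genes of each polymerase comparison, gained or lost members of the fixed lists, and the 5 best-ranked gained regions far from gene ends. Some genes that this rule names are not reported here. The groups, tests, gene lists, named-gene rule and the first set of alternatives were chosen before the data were examined. The BCL6 window, the widest and strongest peaks and the tests of lost list members were chosen after values were seen.

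Alternatives were the stricter q, covered bases, the same number of top peaks per list, 50% cover of a region, a 2.5 kb window, gene-end windows for Ser2P, other backgrounds and references, replicate blocks and leaving out each list. Added after the data were seen were summits in place of peaks, a peak at the same gene end in every treated list, genes that could gain a polymerase form, lost members of the gene lists, leaving out lists for further results, crossed pairing and leaving out replicate 1 of both groups.

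The background behind a peak, in fragments, was solved from its fold and p under the Poisson model of MACS2, for peaks with -log10 p up to 150 and to within 0.001 log10 units. The 5th percentile per list was compared between groups; it was chosen after the lowest value had also been looked at. It stands for the depth at which peaks were called only if the caller scaled libraries in its usual way. The gain calls were tested on simulated data with the 11975 regions of CST2316S in SUDHL5 and 200 planted gains. At 95% detection per list 181 (90.5%) were called with 26 others, and at 80% detection 128 (64.0%) with 307 others. Every simulated list had the same detection, while the real treated and DMSO lists differed in length. The simulation thus does not show how many gains unequal detection between groups would give. The planned motif test was not run, since no genome sequence was at hand. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.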

Results

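CDK-TCIP1 is a bivalent small molecule that binds CDK9, the kinase that releases paused RNA polymerase II into elongation, and BCL6, a transcriptional repressor of germinal-centre B cells. Chromatin immunoprecipitation with sequencing mapped CDK9 and 3 readouts of RNA polymerase II after DMSO or 30 nM CDK-TCIP1 in SUDHL5 and KARPAS422, established lines of diffuse large B-cell lymphoma. CDK9 was mapped at 2 h with antibodies ab239364 and CST2316S in SUDHL5 and with CST2316S in KARPAS422, with 2 DMSO and 2 treated lists in each of these 3 sets. In SUDHL5, the polymerase phosphorylated at serine 2 (Ser2P) or serine 5 (Ser5P) of its C-terminal repeats was mapped with 2 lists, and total polymerase (Pol II) with 3 lists, in each of DMSO at 4 h, CDK-TCIP1 at 2 h and CDK-TCIP1 at 4 h. The 33 deposited peak lists held from 138 to 28951 peaks each. They hold no read totals, so the sequencing depth is unknown, and the length of a list is the only total per sample. Nothing in the labels says that replicates were separate cultures, so p-values of the permutation tests measure only the spread between these samples. Fisher's exact tests run over genes or regions and measure no spread between samples. A region or gene is called gained when every treated list and no DMSO list had a peak there, and lost in the opposite case.

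The first comparison asked where CDK9 was found after CDK-TCIP1 in SUDHL5. With ab239364, 3833 regions were gained and 3 were lost, and with CST2316S 5696 were gained and 0 were lost. Gains at gene ends included CDKN1A (p21) and CDKN1B (p27), both inhibitors of cell-cycle kinases, the growth regulator MYC and the transcription factor IRF2, all 4 with both antibodies. The treated ab239364 lists held 10205 ± 1334 peaks (SD, n = 2) and the DMSO lists 2212 ± 1834 (n = 2), a 5.67-fold ratio of geometric means (2.90-fold and 11.1-fold without DMSO replicates 1 and 2). With CST2316S the treated lists held 9883 ± 173 peaks and the DMSO lists 1438 ± 245 (n = 2 each), a 6.93-fold ratio. Other ways of splitting the same 4 lists into pairs gave at most 192 regions on one side with ab239364 and 12 with CST2316S. Each of those pairs includes a DMSO list, of at most 3508 peaks with ab239364 and 1611 with CST2316S. These splits could thus not reach the real counts of gains, so their low counts follow from list length. The exact permutation test of the list lengths gave p = 0.333 for each antibody, two-sided, the smallest value that 2 against 2 lists can give. Without treated replicate 1, the ab239364 count was 8295 gained regions; the losses were 6, 413 and 23 without treated replicate 2 and DMSO replicates 1 and 2, and with CST2316S 5, 1, 68 and 68 without treated replicates 1 and 2 and DMSO replicates 1 and 2. With the same number of top peaks taken from every list, 182 regions were gained and 100 lost with ab239364, and 443 gained and 116 lost with CST2316S; other splits then gave at most 53 and 23 on one side.

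**Figure D1:**
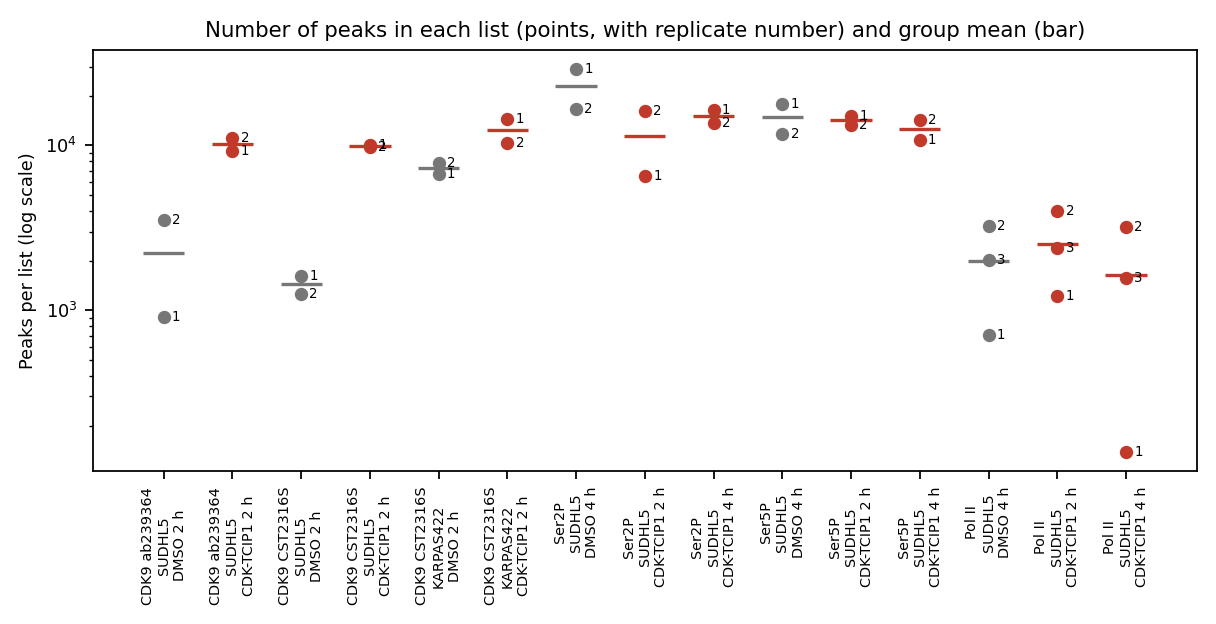
Number of peaks in each deposited list (vertical log axis) by target, cell line and treatment (horizontal axis), grey for DMSO and red for CDK-TCIP1, with the replicate number beside each point and a bar at the group mean. In SUDHL5 the CDK9 lists held 9262 to 11148 peaks after CDK-TCIP1 and 915 to 3508 in DMSO with ab239364, and the Pol II lists of replicate 1 were the shortest of each group.

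BCL6 itself (chromosome 3, 187721377 to 187745468, hg38) had a CDK9 peak at a gene end in all 6 DMSO and all 6 treated lists. In SUDHL5 the peak at the high-coordinate end of BCL6 spanned 4.76 and 2.53 kb in the DMSO lists of ab239364 and 14.3 and 15.1 kb in its treated lists. With CST2316S the spans were 9.62 and 8.80 kb in DMSO and 15.9 and 16.4 kb in treated SUDHL5, against 13.6 and 13.5 kb in DMSO and 14.5 kb in both treated lists of KARPAS422. A second domain lay between BCL6 and LPP, over the long noncoding RNA gene LINC01991 (187958775 to 187976407). There the widest peak of each treated CST2316S list of SUDHL5 spanned 62.6 kb (187926123 to 187988746) and 64.0 kb (187924809 to 187988776). Over chromosome 3 from 187700000 to 188000000, a window chosen after the peaks were seen, peaks covered 17.04 ± 4.29 kb in DMSO and 84.9 ± 18.4 kb after CDK-TCIP1 with ab239364 (SD, n = 2 each). With CST2316S they covered 58.3 ± 1.89 and 115.4 ± 0.388 kb in SUDHL5, and 76.7 ± 9.04 and 81.6 ± 12.1 kb in KARPAS422 (DMSO and treated, SD, n = 2 each). The exact permutation tests of these lengths gave p = 0.333, 0.333 and 0.667, two-sided, and 0.333 is the smallest value possible. Over all peaks the covered length rose more, 9.11-fold, 10.96-fold and 1.65-fold in the same order (ratios of geometric means; the first was 4.79-fold and 17.3-fold without DMSO replicates 1 and 2). The window held 2.45% and 0.972% of all covered bases in the DMSO lists of ab239364 and 0.917% and 0.781% in its treated lists. With CST2316S these shares were 3.80% and 4.39% in DMSO and 0.748% and 0.728% in treated SUDHL5, and 0.864% and 0.767% in DMSO and 0.460% and 0.595% in treated KARPAS422. The rise in cover of the window was thus smaller than that of the whole lists. With CST2316S in SUDHL5, a 10.96-fold rise from 58.3 kb would exceed the length of the window. A smaller rise and a lower share were therefore fixed beforehand there, and do not show a weaker response of this locus. With ab239364 and in KARPAS422 the window had room for the rise of the whole lists, but it was chosen after the peaks were seen.

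**Figure D2:**
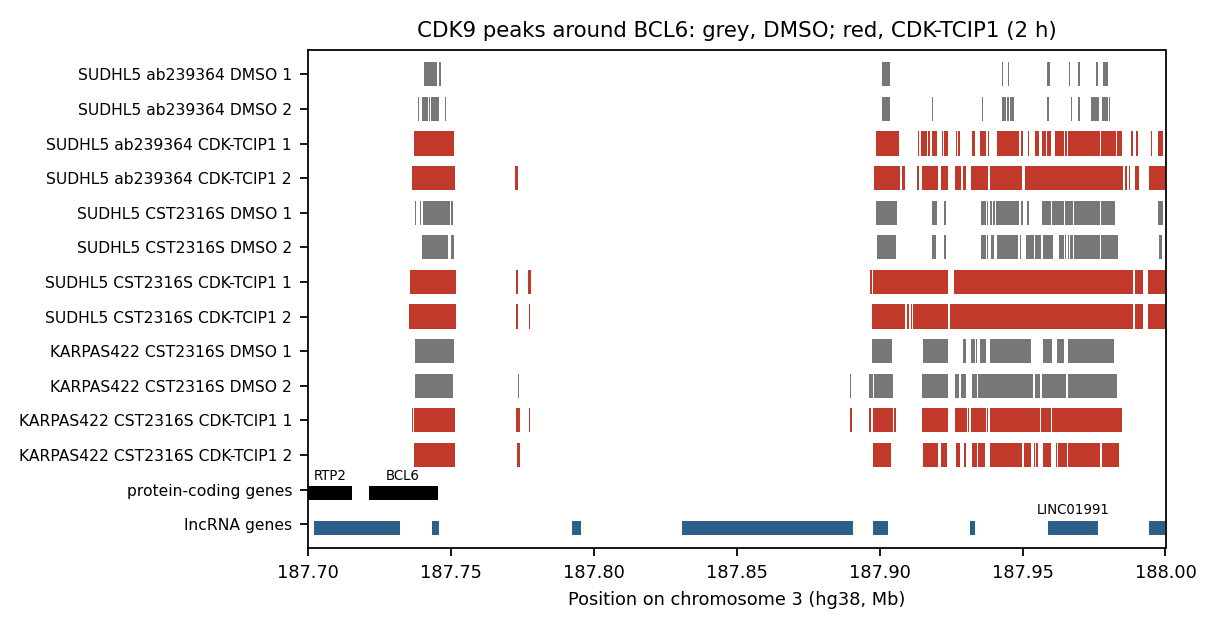
CDK9 peaks of the 12 CDK9 lists (rows, labelled by cell line, antibody, treatment and replicate) along chromosome 3 in Mb (horizontal axis, hg38), with protein-coding and long noncoding RNA genes in the bottom rows. Bars are peaks, grey for DMSO and red for CDK-TCIP1; the treated CST2316S lists of SUDHL5 covered 115.4 ± 0.388 kb of the window and the DMSO lists 58.3 ± 1.89 kb (SD, n = 2).

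At protein-coding genes, taken within 1 kb of either gene end, CDK9 was gained at 1516 genes with ab239364 and 1265 with CST2316S in SUDHL5, and lost at 2 and 0. IRF2 (chromosome 4, 184387729 to 184474550) led both rankings: its peaks had 19.7-fold and 28.3-fold enrichment in the treated ab239364 lists and 40.8-fold and 49.6-fold in the treated CST2316S lists. These enrichments are the authors' values for a peak and rank it only within its own list. With CST2316S the next were TBL1XR1, a subunit of corepressor complexes (59.4-fold and 93.4-fold), TRIM2, LPP, GNPTAB, ENO3 and PFN1 (which share a window), SLC35D4, RPIA and PRH1. With ab239364 they were TMEM107, ADAMTSL4, MITD1 and MRPL30 (shared window), SLC35D4, ENOPH1, GNPTAB, DTX3L and PARP15. The antibodies shared 537 gained genes among the 8011 genes without a DMSO peak in either set. Independent lists would share 137.1 (Fisher's exact test, two-sided, odds ratio 17.01, p = 4.58e-257). Those 8011 genes held 755 of the 1265 CST2316S gains and 1455 of the 1516 ab239364 gains. The other CST2316S gains, HEXIM1 among them, had an ab239364 peak in DMSO, so gained does not mean that CDK9 was absent before. The labels give both antibodies the same replicate numbers and do not say whether they were used on the same chromatin. Equal numbers of top peaks from every list left 38 genes gained and 126 lost with ab239364, so the direction turned there, and 126 gained and 93 lost with CST2316S, with 17 gains shared. The ab239364 count was 2412 without treated replicate 1, 2339 without treated replicate 2 and 3012 without DMSO replicate 2, and the shared count was 917 without the last of these.

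Genes of the cell-cycle arrest list gained CDK9 more often than other genes in 1 set. With CST2316S in SUDHL5, 9 of the 17 members without a DMSO peak were gained (52.9%, against 12.2% of other genes; Fisher's exact test, odds ratio 8.13, adjusted p = 0.00775), among them CDKN1A, CDKN1B, CDKN2A, CDKN2C, MDM2, GADD45A, BTG1 and RB1. They differ in function: MDM2 is a ubiquitin ligase, and RB1 restrains entry into S phase. With ab239364, 5 of 12 members were gained (Fisher's exact test, odds ratio 3.10, adjusted p = 0.514), including CDKN1A and CDKN1B, and in KARPAS422 1 of 10 (CDKN2C, adjusted p = 1). It was the 1 call among 135 tests of 15 lists fixed before the data were examined (11 at an unadjusted p under 0.05), and without treated replicate 2 of CST2316S its adjusted p was 0.0548. Counting only genes with a peak at the same gene end in every treated list, an alternative added after the data were seen, kept 1263 of the 1265 genes but not GADD45A. The list then gave 8 of 17 (Fisher's exact test, odds ratio 6.43, adjusted p = 0.0571), and no list passed the threshold.

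Known BCL6 targets were gained at 7 of 16 members in each SUDHL5 set (43.8%, against 18.7% of other genes with ab239364 and 12.2% with CST2316S), with adjusted p = 0.450 and 0.114 by Fisher's exact test. CDKN1A, CDKN1B, NFKB1, ID2 and CXCR5 were among those in both sets, and CDKN1A and CDKN1B also belong to the cell-cycle list. Germinal-centre B-cell genes gave 7 of 13 with ab239364 and 6 of 13 with CST2316S (Fisher's exact test, adjusted p = 0.162 and 0.119), with CD22, IRF8, CD37 and CD38 among those in both. This list passed the threshold with a 2.5 kb window (adjusted p = 0.00162 with ab239364 and 0.0143 with CST2316S) and with all protein-coding genes as background (0.00523 and 0.00621, Fisher's exact tests). It also passed with -log10 q of at least 5 (0.0245 with CST2316S) and without DMSO replicate 2 of ab239364 (0.0418 with ab239364, Fisher's exact tests), so its call depends on the setting. Another 13 members had a peak in every CST2316S list of SUDHL5 and could not be gained. Among pro-apoptotic genes, 5 of 17 were gained with ab239364 (BAD, BAX, TNFRSF10A, CYCS and TP53INP1) and 6 of 22 with CST2316S (Fisher's exact test, adjusted p = 1 and 0.514). The CST2316S gains were BCL2L11 (BIM), PMAIP1 (NOXA) and BBC3 (PUMA), all activators of mitochondrial apoptosis, the death receptors TNFRSF10A and TNFRSF10B, and TP53INP1. With ab239364, BCL2L11, PMAIP1 and TNFRSF10B had a peak in both treated lists and in 1 of 2 DMSO lists.

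No other list passed the adjusted threshold in SUDHL5 (smallest adjusted p = 0.450, Fisher's exact tests). Immediate-early genes gave 5 of 10 members with ab239364 (JUN, EGR3, IER5, DUSP5 and MYC) and 5 of 16 with CST2316S (JUNB, JUND, EGR3, DUSP5 and MYC). NF-kB genes gave 4 of 10 (NFKB1, RELA, TRAF1 and CD86) and 4 of 12 (NFKB1, NFKBIA, NFKBIZ and CD86), in the same order of antibodies. Plasma-cell genes gave 4 of 7 (XBP1, JCHAIN, TNFRSF17 and HSPA5) and 2 of 6 (XBP1 and TNFRSF17). MYC and growth genes gave 3 of 7 (MYC, LDHA and CDK4) and 3 of 13 (MYC, HSPD1 and NOP56), and FOXO genes 1 of 7 (FOXO3) and 3 of 9 (CITED2, KLF6 and PIK3IP1). The P-TEFb and super elongation complex list gave 2 of 7 (AFF4 and CDK13) and 2 of 17 (HEXIM1 and HEXIM2, inhibitors of CDK9). HEXIM1 had an ab239364 peak in both DMSO lists. BCL6 corepressors gave 2 of 8 and 1 of 10, with HDAC7 in both, and anti-apoptotic genes 2 of 6 (BIRC2 and BIRC5) and 0 of 6. T-cell markers gave 0 of 2 and 1 of 3 (LCK), myeloid markers 1 of 3 (CD68) and 0 of 3, and silent tissue genes 0 of 1 with each antibody.

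**Figure D3:**
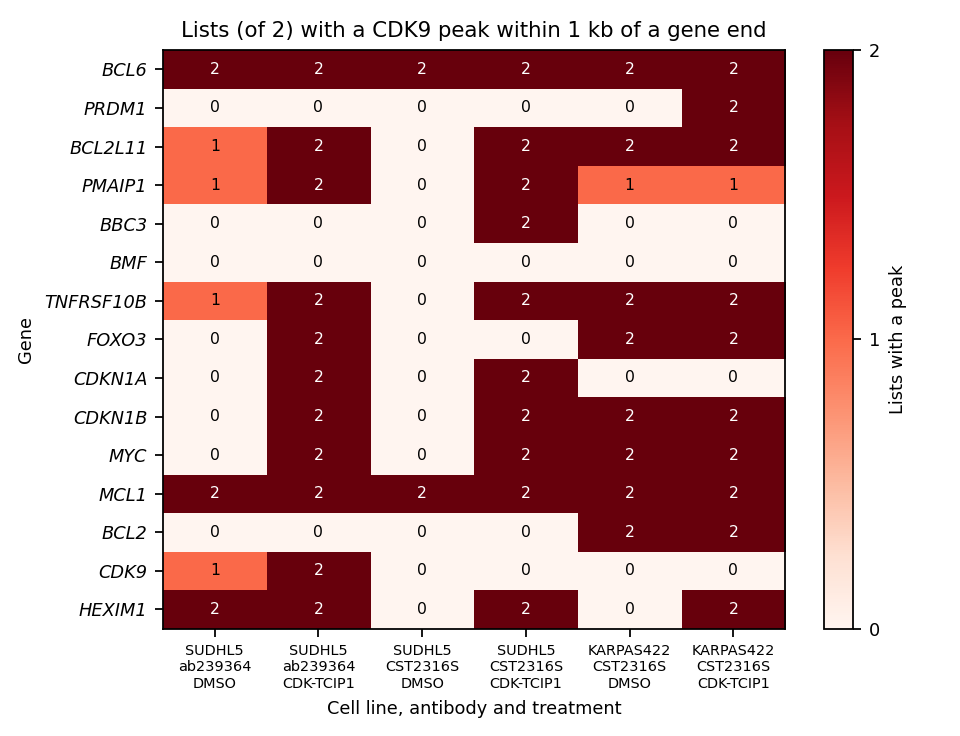
Number of lists, out of 2, with a CDK9 peak within 1 kb of an end of each of 15 genes fixed beforehand (rows), by cell line, antibody and treatment (columns). BCL6 and MCL1 had a peak in all 12 lists, CDKN1A in all 4 treated SUDHL5 lists and in 0 of the 6 DMSO lists, and BMF in 0 lists.

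In KARPAS422, 548 of the 1516 genes gained with ab239364 in SUDHL5 (36.1%) and 689 of the 1265 gained with CST2316S (54.5%) had a CDK9 peak in every list, DMSO included. Of the other genes without a SUDHL5 DMSO peak 8.09% and 12.4% did, in the same order. CDKN1B, MYC, BCL2L11, TNFRSF10B and FOXO3 had peaks in both DMSO lists and both treated lists, PMAIP1 in 1 of each, and CDKN1A and BBC3 in 0 lists. PRDM1 (BLIMP1), the plasma-cell regulator that BCL6 represses, was gained in KARPAS422 and had no peak at a gene end in the 8 SUDHL5 lists. As for the other genes here, peaks further inside the gene were not counted. In all, 2675 regions were gained and 206 lost, with 877 genes gained and 126 lost. The leading genes were CYB5B (24.9-fold and 25.2-fold), ICE2, a subunit of the little elongation complex (29.2-fold and 16.5-fold), PAN2, ZNF227, CMTR2, PTPRT, TARS1, MITD1 and MRPL30, and DYNC2I1. The gained members of the fixed lists included PRDM1, NFKB1 and KLF2 among BCL6 targets (3 of 10), CASP10 among pro-apoptotic genes (1 of 12), IKZF1 and LMO2 among germinal-centre genes (2 of 6), and KLF2 and CCNG2 among FOXO genes (2 of 6). PRDM1 and XBP1 were gained among plasma-cell genes (2 of 6), CCND3 among MYC and growth genes (1 of 4), HEXIM1 in the P-TEFb list (1 of 7), DUSP2 among immediate-early genes (1 of 6) and NFKB1 among NF-kB genes (1 of 10). Anti-apoptotic genes gave 0 of 2, myeloid markers 0 of 2, silent tissue genes 0 of 1 and T-cell markers 0 of 0, and the smallest adjusted p was 0.859 (Fisher's exact tests). The treated lists held 12426 ± 3010 peaks and the DMSO lists 7247 ± 788 (SD, n = 2 each), a 1.69-fold ratio (exact permutation test, two-sided, p = 0.333, the smallest possible). Other splits of the 4 lists gave at most 520 regions. With the same number of top peaks from every list, 1191 regions were gained and 692 lost, while 359 genes were gained and 506 lost, so that by gene the direction turned. Without treated replicate 2 the gains were 7494 regions and 1816 genes, and without DMSO replicate 2 1364 genes; the losses were 608, 1096 and 820 regions without treated replicate 1, DMSO replicate 1 and DMSO replicate 2.

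The log2 ratio of list length with CST2316S was 2.03 higher in SUDHL5 than in KARPAS422 (exact permutation within each line, two-sided, p = 0.333). The treated lists were the longest in both lines, so this permutation could give no smaller p however large the difference. It thus does not decide whether the lines differ. Over the 3 sets the mean log2 ratio was 2.02, with longer treated than DMSO lists in 6 of 6 pairs of equal replicate number. With both SUDHL5 antibodies permuted together, the exact two-sided permutation p was 0.0556, the smallest that 36 relabellings can give. Permuted separately it was 0.00926, which counts the antibodies as independent.

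Across the sets, 94 genes and 279 regions were gained in all 3. The 10 leading genes were CYB5B, ICE2, MITD1 and MRPL30, ZNF227, TARS1, ADAMTSL4, SLC35D4, FRA10AC1 and TICRR. KARPAS422 shared 189 gained genes with ab239364 (68.9 for independent lists, odds ratio 4.58, p = 1.49e-45) and 185 with CST2316S in SUDHL5 (48.2, odds ratio 8.23, p = 1.21e-71; Fisher's exact tests, two-sided). Without DMSO replicate 2 of KARPAS422 these counts were 320 and 289, and the first was 327 without DMSO replicate 2 of ab239364; with the same number of top peaks from every list they were 5 and 16. Over regions, the antibodies shared 1959 gains in SUDHL5 (1155.1 for independent lists, odds ratio 4.43, p = 9.85e-259), and ab239364 shared 412 with KARPAS422 (352.9, odds ratio 1.27, p = 0.000177; Fisher's exact tests). By region CST2316S shared 693 gains between the lines among regions without a DMSO peak in either line. Independent lists would share 664.2 (Fisher's exact test, odds ratio 1.07, p = 0.152). Every region tested held a peak in some CDK9 list, which raises the number for independent lists. Over regions the lack of an excess thus decides nothing. Of the 279 common regions, 167 lay over 1 kb from any annotated gene end. The 5 leading ones, in hg38, were chromosome 3 from 187038786 to 187045301 within ST6GAL1, chromosome 3 from 46536558 to 46540268 within LRRC2 and chromosome 2 from 11752643 to 11756158 within LPIN1. The others were chromosome 12 from 9740014 to 9744160, 5668 bp from CLECL1, and chromosome 2 from 136211851 to 136214467, whose nearest protein-coding gene, CXCR4, a chemokine receptor, was 93702 bp away.

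CDK9 peaks in SUDHL5 DMSO cells with ab239364 lay at gene ends in 64.8% ± 2.81 of cases, against 41.9% ± 4.95 after CDK-TCIP1 (SD, n = 2 each). With CST2316S the shares were 22.1% ± 0.869 and 20.3% ± 0.661 in SUDHL5, and 41.2% ± 0.428 and 34.4% ± 1.70 in KARPAS422, in DMSO and treated lists (n = 2 each). Each exact permutation test, two-sided, gave p = 0.333, the smallest possible.

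The polymerase comparisons asked whether its forms moved with CDK-TCIP1 in SUDHL5; both treated times were set against the same DMSO lists of 4 h. For Ser5P, the form found at transcription start, 548 genes were gained and 52 lost at 2 h, and 280 were gained and 84 lost at 4 h. FOXO3, a transcription factor of stress and survival genes, and SESN3, one of its targets, were gained at both times (2 of 5 FOXO members, Fisher's exact test, adjusted p = 0.994 and 0.526). IER3 was gained at both times, CHEK1 and CTBP1 at 2 h, and DIABLO, a mitochondrial pro-apoptotic protein, was lost at both times. The leading gains at 2 h were NOSIP, APLP2, DAPP1, DBR1 and PSME2, and at 4 h NOSIP, DAPP1, TNFRSF10D, a decoy death receptor, DBR1 and ZNF852. The leading losses were MYH14, SH3GLB2, SMIM35, PIP5KL1 and ZNF768 at 2 h and MIEF1, MYH14, JCHAIN, SH3GLB2 and SMIM35 at 4 h. BCL6, BCL2L11, PMAIP1, TNFRSF10B, CDKN1B, MYC, MCL1, CDK9 and HEXIM1 had Ser5P peaks in all 6 lists. List lengths were 14783 ± 4244 in DMSO, 14195 ± 1279 at 2 h and 12527 ± 2419 at 4 h (SD, n = 2 each; exact permutation, two-sided, p = 1 and 0.667). The other splits gave at most 201 genes on one side at 2 h and 494 at 4 h, the second above the real count. Without treated replicates 1 and 2 and DMSO replicates 1 and 2 in turn, 1055, 850, 1553 and 891 genes were gained at 2 h; at 4 h 1173, 996 and 484 were gained without treated replicate 1 and DMSO replicates 1 and 2.

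By region, Ser5P gave 894 gains and 658 losses at 2 h and 479 gains and 864 losses at 4 h, and other splits gave up to 1223 and 945. Equal numbers of top peaks gave 954 regions gained and 598 lost at 2 h and 714 gained and 635 lost at 4 h, so that the excess of losses at 4 h turned. Of the gained regions 60.1% at 2 h and 55.9% at 4 h overlapped a gene end, and of the lost ones 18.8% and 21.3%. In the other splits these shares ran from 20.7% to 51.2% at 2 h and from 22.6% to 52.5% at 4 h. Leaving out lists moved these counts by over 1.5 times: at 2 h to 2558, 3428 and 2358 gains without treated replicates 1 and 2 and DMSO replicate 1, and to 1201, 1922 and 5983 losses without treated replicate 1 and DMSO replicates 1 and 2. At 4 h the gains were 3326, 1484, 1545 and 733 without treated replicates 1 and 2 and DMSO replicates 1 and 2, and the losses 1817, 2185 and 6812 without treated replicate 2 and DMSO replicates 1 and 2.

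For Ser2P, which marks elongating polymerase and was counted over the gene and 2 kb on either side, 27 genes were gained and 397 lost at 2 h, and 274 were gained and 242 lost at 4 h. HRK, a pro-apoptotic BH3-only protein, was gained at both times and BMF, another, at 4 h (1 and 2 of 4 pro-apoptotic members, Fisher's exact test, adjusted p = 0.514 and 0.765). XIAP, an inhibitor of caspases, was lost at 2 h and CSF1R at both times. The leading gains were LOC124905345, ABHD17B and C9orf85 (shared window), FH and MRPS31 at 2 h, and H1-6, RAB18, CCHCR1 and TCF19 (shared window) and AQR at 4 h. The leading losses included MPIG6B, RFNG, TMEM161A, RAB24 and ENAM at 2 h and AGK, TP53I11, ENAM and MC1R at 4 h. BCL6, BCL2L11, PMAIP1, BBC3, TNFRSF10B, CDKN1A, CDKN1B, MYC, MCL1, CDK9 and HEXIM1 had Ser2P peaks in all 6 lists. The lists held 22772 ± 8738 peaks in DMSO, 11345 ± 6824 at 2 h and 14990 ± 1885 at 4 h (SD, n = 2 each; exact permutation, two-sided, p = 0.333 for both, the smallest possible). By region, 82 were gained and 2714 lost at 2 h and 636 gained and 2122 lost at 4 h, and other splits gave up to 2180 and 1750 on one side; by gene they gave up to 1170 and 443, more than the real counts. Equal numbers of top peaks gave 407 regions gained and 578 lost at 2 h and 1194 gained and 991 lost at 4 h. By gene 328 were then gained and 186 lost at 2 h and 703 gained and 127 lost at 4 h. The excess of losses thus depended on list length: by region it shrank at 2 h and turned at 4 h, and by gene it turned at 2 h.

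The difference in Ser2P list length at 2 h rested on replicate 1, with 6519 peaks in the treated list and 28951 in DMSO; replicate 2 had 16170 and 16593. Without treated replicates 1 and 2 and DMSO replicates 1 and 2 in turn, 640, 69, 270 and 49 genes were gained at 2 h and 569, 594, 1280 and 438 at 4 h. The gained regions were then 3379, 432, 452 and 141 at 2 h and 2341, 3234, 2059 and 1004 at 4 h. Lost regions were 6447, 6240 and 16229 at 2 h without treated replicate 2 and DMSO replicates 1 and 2, and 3487, 5501 and 14595 at 4 h without treated replicate 1 and DMSO replicates 1 and 2. Peaks at gene ends made up 37.2% ± 4.40 of the DMSO lists, 50.8% ± 0.885 at 2 h and 50.3% ± 4.24 at 4 h (SD, n = 2 each; exact permutation, two-sided, p = 0.333 for both).

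Pol II was gained at 34 genes and lost at 1 (IPO7) at 2 h. At 4 h it was gained at 0 and lost at 6, among them IPO7, ELAC1, MZB1 and PROB1 (shared window) and SLC7A1. The gains included HES6, FNTA, CYP20A1, EBF1, a B-cell transcription factor, EZR, TNFRSF10A and DUSP1, each in all 3 treated lists and 0 of 3 DMSO lists. CDKN1B had a Pol II peak in 2 of 3 lists at 2 h and at 4 h and in 0 of 3 DMSO lists, while BCL2L11 and HEXIM1 had one in all 9 lists. The lists held 1989 ± 1260 peaks in DMSO, 2533 ± 1399 at 2 h and 1635 ± 1530 at 4 h (SD, n = 3 each; exact permutation, two-sided, p = 0.6 for both; 0.1 is the smallest possible). Other splits of the 6 lists gave up to 192 and 396 genes on one side, more than the real counts. By region, 32 were gained and 2 lost at 2 h and 1 was gained and 9 were lost at 4 h. Without treated replicates 1 and 3 and DMSO replicate 2, the regions gained at 2 h were 246, 83 and 104, and without treated replicate 2 and DMSO replicates 1 and 3 those lost were 25, 72 and 10. At 4 h the gains were 111 and 2 without treated replicate 1 and DMSO replicate 2, and the losses 75, 15, 139 and 26 without treated replicates 2 and 3 and DMSO replicates 1 and 3. Without replicate 1 of DMSO the log2 ratio at 2 h turned from 0.44 to -0.18, and without treated replicate 1 that at 4 h turned from -0.92 to 0.43. The genes gained at 2 h were 241, 79 and 99 without treated replicates 1 and 3 and DMSO replicate 2, and at 4 h 106 and 2 without treated replicate 1 and DMSO replicate 2.

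Of the 537 genes that gained CDK9 with both antibodies, 76.4% had a Ser5P and 72.3% a Ser2P peak in both DMSO lists. A Pol II peak in all 3 DMSO lists was held by 5.40%. That share is low partly because DMSO replicate 1 held only 710 peaks, against 3229 and 2028. In no DMSO list was a Pol II peak found at 326 of the 537 genes. Of all 537 genes 3.35% gained Ser5P at 2 h and 1.49% at 4 h, 0.559% and 2.61% gained Ser2P, and 1.304% and 0% gained Pol II. The planned reference, 132 genes with CDK9 in every SUDHL5 list, gained 0% for Ser5P and Ser2P and 0.758% and 0% for Pol II (Fisher's exact tests, smallest adjusted p = 0.191). All 132 had Ser5P and Ser2P in both DMSO lists, so that a gain there was impossible and those 4 tests decide nothing. Against the other 8764 genes with a Ser5P peak in any list, the share of genes that gained Ser5P at 2 h was lower among the CDK9-gained genes (3.35% and 6.05%, Fisher's exact test, adjusted p = 0.0239) and Pol II gains at 2 h more frequent (7 genes, 1.304%, and 27 genes, 0.308%, adjusted p = 0.0170). Only 57.5% of those other genes had Ser5P in both DMSO lists, so more of them could gain it; 66.5% had Ser2P in both and 4.86% Pol II in all 3. The Pol II test rests on the 34 genes gained at 2 h, a count that other splits exceeded.

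The direction turned among genes that could gain, those without a DMSO peak of the polymerase form, a comparison added after the data were seen. Ser5P at 2 h was then gained at 18 of 52 CDK9-gained genes (34.6%) and at 16.6% of the other 3192 (Fisher's exact test, odds ratio 2.66, adjusted p = 0.00422; 0.0562 without treated replicate 1 of Ser5P). In the mixed splits of the same Ser5P lists the smallest p was 0.453 (Fisher's exact tests). Those splits held 28 to 34 CDK9-gained genes that could gain, with 0 to 3 of them on one side. They could hardly give a small p, so they do not show that the association is particular to the treatment. At 4 h the shares were 15.4% and 8.52% (adjusted p = 0.100), and p was 0.00503 in a mixed split (Fisher's exact tests). That call at 4 h passed without treated replicate 1 or DMSO replicate 2 of ab239364 (0.0396 and 0.0385), treated replicate 1 of CST2316S (0.0452) or DMSO replicates 1 and 2 of Ser5P (1.19e-05 and 0.00765, Fisher's exact tests). For Ser2P the shares were 5.45% (3 of 55 genes) and 0.900% at 2 h and 25.5% and 9.75% at 4 h (Fisher's exact tests, adjusted p = 0.0243 and 0.00227). The first was 0.0733 without treated replicate 2 and 0.0933 without DMSO replicate 1 of Ser2P (Fisher's exact tests). For Pol II they were 2.15% and 0.359% at 2 h (adjusted p = 0.00227) and 0% and 0% at 4 h, where the adjusted p was 1.75e-06 without treated replicate 1 of Pol II (Fisher's exact tests). For Ser2P at 4 h the real split gave an unadjusted p of 0.000758 (14 of 55 genes, odds ratio 3.16). The smallest p of a mixed split was 0.0495 there (13 of 63 genes, odds ratio 1.90, Fisher's exact tests). Few such splits exist, so this is no test of the treatment. Mixed splits gave smaller p than the real split for Ser2P at 2 h (9.06e-07) and Pol II at 2 h and 4 h (1.30e-06 and 7.92e-06, Fisher's exact tests). Those 3 mixed splits held more genes on one side (50 of 117, 25 of 388 and 20 of 417), which lowers p. At 2 h their odds ratios were 2.63 for Ser2P and 3.35 for Pol II, against 6.36 and 6.09 in the real splits. An association thus also arose in splits that mix the groups. Whether it is stronger with the treatment cannot be told from these p-values, and at 4 h the real Pol II split held 0 genes.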

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

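The tests of list length and summits for Ser5P were planned before their results were seen; all the other tests in this part were chosen after. The log2 ratio of Pol II list length to DMSO was lower at 4 h than at 2 h (difference -1.35, exact sign-flip test, two-sided, p = 0.25, the smallest possible). It drew attention because all 3 pairs of equal number were higher than DMSO at 2 h (0.77, 0.31 and 0.23) and all 3 lower at 4 h (-2.36, -0.01 and -0.37). Both times share the DMSO lists, and without DMSO replicate 1 the 2 h value was -0.18, without treated replicate 1 the 4 h value 0.43.

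CDK9 lists of SUDHL5 were 5.67-fold and 6.93-fold longer after CDK-TCIP1, the first 2.90-fold and 11.1-fold without DMSO replicates 1 and 2 of ab239364. The recovered background barely differed with treatment: its highest treated to DMSO ratio over both antibodies was 1.02, below a cut of 1.5. With ab239364 it was 2.12 and 3.4 fragments in the treated lists (9262 and 11148 peaks). In the DMSO lists it was 2.17 and 3.215 (915 and 3508 peaks). The cut was set after the data were seen, and what ratio depth would need is unknown. Greater depth of the treated libraries is thus argued against only as far as this background stands for depth. A uniform rise in enrichment that keeps the order of peaks was tested by searching the longer DMSO list for the peaks of the other DMSO list and for as many top treated peaks; the reverse search is capped by the length of the shorter list. With CST2316S the treated peaks were found less often by 12.6 and 12.7 percentage points, and the treated lists differed by 0.158. That argues against such a rise as the whole cause there. The limit is that the share found of the other DMSO list (64.7%) rests on 1 pair of lists, whose spread is unknown. With ab239364 the lower difference was 5.79 points and the treated lists differed by 7.43, so the rise cannot be told apart from a redistribution there. What stays open is a redistribution of CDK9 by CDK-TCIP1, which may account for the gains, and differences in immunoprecipitation between samples, which were not tested. With the top 915 peaks of every ab239364 list, 126 genes counted as lost and 38 as gained. With all peaks 2 were lost and 1516 gained, so nearly all of the 126 kept a peak in a full treated list. They left the top ranks, which is not a loss of CDK9.

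Ser5P gains outnumbered losses at gene ends at 2 h, with 548 and 52 genes. With the same number of top peaks the ratio was 10.55, with summits in the window 9.86, and the background ratio was 1.11, so that unequal list lengths, wider treated peaks and greater depth were each argued against. The other splits gave ratios of the larger to the smaller side of 1.44 and 5.91, and at 4 h of 3.57 and 82.3, both above the real 3.33. With 3 splits of 4 lists, and 494 genes in another split at 4 h against 280 gained, a difference between single lists may also contribute, and the 2 h lists differ from DMSO in time as well as in treatment.

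The Pol II lists of replicate 1 were the shortest of each of the 3 groups, but had the lowest background in 0 of them, which argues against lower depth. The splits of 6 lists are too few (10) for a share under 0.05. In 6 of the 10 splits as many regions were gained plus lost: 34 at 2 h with at most 211 in another split, and 10 at 4 h with at most 378. For genes the real counts were 35 and 6 and the highest others 192 and 396, also in 6 of 10. The highest splits, several times the real counts, put the replicate 1 lists together. All their regions lay on the other side (211 at 2 h and 378 at 4 h), with 0 on the side of the replicate 1 lists. These counts thus go with the shortness of the replicate 1 lists, not with regions that those lists share. No biological explanation was tested for the short lists.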

How the results depend on the processing

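Leaving out lists was added after the data were seen for the gene lists, overlaps, peak location, line difference and CDK9 against polymerase, as were the summit, same-gene-end, genes-that-could-gain and crossed-pairing alternatives and leaving out replicate 1 of both groups; the other alternatives were planned. Of 503 alternative values, 356 kept their direction and side of the threshold or their size, 2 were weaker, 9 were stronger, 10 reversed and 126 moved. Counts rise by construction when a list is left out, since fewer lists must hold or lack a peak; for the other changes the cause was not tested. The read depth, which is unknown, limits all counts, and 2 against 2 lists cannot reach the threshold by exact permutation. The planned motif test was not run. With labels exchanged only within pairs of equal number (a replicate block) the combined CDK9 p was 0.125 with antibodies permuted together and 0.0312 (mean log2 ratio 2.02) separately, and without the block 0.00926 separately (2.02), by exact permutation. With crossed numbers, 2 of 2 ab239364 pairs were still longer after treatment. By their labels the lists share only a number. Correlations of same-numbered deviations ran from 0.0260 to 0.139 for Ser2P and from 0.0562 to 0.129 for Ser5P (6 of 6 positive each). With 2 lists per group each value occurs in duplicate by construction, so these are not 6 separate values. For Pol II they ran from -0.00681 to 0.160 (8 of 9 positive). Not every one exceeded the 0.1 taken as pairing. They were -0.136, 0.00227 and 0.0248 for the CDK9 sets (ab239364, CST2316S and KARPAS422). In 12 of 18 comparisons a Pol II list correlated best with its own number. Ser2P and Ser5P lists did so in 12 of 12 each, CST2316S lists in 4 of 4 in each line and ab239364 lists in 0 of 4. With 2 lists per group these counts also repeat the same values by construction.

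With -log10 q of at least 5, the log2 ratio of Ser5P list length at 2 h was 0.22, and with covered bases 0.10. The stricter q gave 1 lost region with ab239364, 46 gained and 1162 lost for Ser2P at 2 h, 816 lost for Ser2P at 4 h, and 305 and 420 lost for Ser5P at 2 h and 4 h. It gave 20 gained and 0 lost for Pol II at 2 h and 0 gained and 2 lost at 4 h. Gained genes were 557 for Ser2P at 4 h, 843 for Ser5P at 2 h and 18 for Pol II at 2 h, and 2 gene lists passed. The difference of CDK9-gained genes from the reference was then 8.71 points for Ser5P at 2 h (Fisher's exact test, adjusted p = 0.0182) and -0.818 for Pol II at 2 h. Of the 76 reference genes 0 could gain Ser5P and 7 Pol II in that setting, so the first value decides nothing.

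With the same number of top peaks, gained and lost regions were 182 and 100 (ab239364), 443 and 116 (CST2316S in SUDHL5), 1191 and 692 (KARPAS422), 407 and 578 (Ser2P at 2 h), 1194 and 991 (Ser2P at 4 h), 954 and 598 and 714 and 635 (Ser5P at 2 h and 4 h) and 14 and 6 (Pol II at 2 h), with 2 lost for Pol II at 4 h. The balance of gained and lost regions turned for Ser2P and Ser5P at 4 h, and that of genes for ab239364, KARPAS422 and Ser2P at 2 h. Gained genes were 38, 126 and 359 for the CDK9 sets, 328 and 703 for Ser2P, 457 for Ser5P at 4 h and 13 for Pol II at 2 h, and the overlaps 17, 5 and 16. With 50% cover, gained regions were 1093 for Ser2P at 4 h and 1550 and 723 for Ser5P. All protein-coding genes as background gave 5 gene lists past the threshold, among them BCL6 targets with CST2316S (adjusted p = 0.0205) and immediate-early genes with ab239364 (0.0409, Fisher's exact tests), and the 2.5 kb window 3. With a peak required at the same gene end in every treated list, 1494, 1263 and 876 genes gained CDK9 and 543 and 277 Ser5P, but 0 gene lists passed: the log2 odds ratio of the cell-cycle list was 2.68 (Fisher's exact test, adjusted p = 0.0571), because GADD45A had its treated CST2316S peaks at different ends. CD68 with ab239364 was the other named gene of this kind. With other Ser5P genes as the reference the differences were -2.70 and -1.61 points for Ser5P at 2 h and 4 h and 0.995 for Pol II at 2 h. The negative values include genes that could not gain. Among genes that could, the differences were 18.01 and 6.86 points for Ser5P, 4.555 and 15.7 for Ser2P at 2 h and 4 h, and 1.79 for Pol II at 2 h.

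Leaving out 1 list gave log2 ratios of list length of 1.53 to 3.47 (ab239364), 2.62 to 2.97 (CST2316S), 0.51 to 1.01 (KARPAS422), -1.75 to -0.44 and -0.96 to -0.15 (Ser2P at 2 h and 4 h), -0.33 to 0.27 and -0.52 to 0.0748 (Ser5P) and -0.18 to 0.91 and -1.84 to 0.43 (Pol II). Ser5P at 2 h turned to 0.06 without treated replicate 2 and 0.27 without DMSO replicate 1, and at 4 h to 0.0748 without DMSO replicate 1; Pol II turned to -0.18 at 2 h without DMSO replicate 1 and 0.43 at 4 h without treated replicate 1. Without replicate 1 of both groups the values were -0.04 and -0.28 (Ser2P) and 0.27 and -0.19 (Pol II). The combined value was 1.70 to 2.34 and the line difference 1.78 to 2.28. Gained regions were 3889 to 8295, 5899 to 8143 and 3133 to 7494 (CDK9 sets), 141 to 3379 and 1004 to 3234 (Ser2P), 1332 to 3428 and 733 to 3326 (Ser5P) and 33 to 246 and 1 to 111 (Pol II). Lost regions were 4 to 413, 1 to 68 and 247 to 1096, 2904 to 16229 and 2634 to 14595, 926 to 5983 and 1136 to 6812, and 2 to 72 and 9 to 139, in the same order. Gained genes were 1553 to 3012, 1341 to 1774, 1104 to 1816, 49 to 640, 438 to 1280, 850 to 1553, 357 to 1173, 35 to 241 and 0 to 106. Gene lists past the threshold were 0 to 2, with BCL6 targets (CST2316S, adjusted p = 0.0408, Fisher's exact test) without DMSO replicate 2 of CST2316S, and the log2 odds ratio of the cell-cycle list 2.45 to 3.09, the lowest (Fisher's exact test, adjusted p = 0.0548) without treated replicate 2 of CST2316S. CDK9 against polymerase gave 0.436 to 0.750 and 1.74 to 2.55 points (Ser2P), 2.40 to 4.01 and 1.09 to 2.10 (Ser5P) and 0.257 to 0.787 and 0 to 0 (Pol II), and Ser5P at 2 h passed the threshold at 3.30 without DMSO replicate 1 of ab239364 (Fisher's exact test, adjusted p = 0.0323), where 0 of 202 reference genes could gain it, so that this decides nothing. Overlaps were 546 to 917, 192 to 327 and 187 to 289. Location differences were -26.4 to -19.4, -2.39 to -1.17 and -8.01 to -5.60 points (CDK9 sets), 10.5 to 16.7 and 9.93 to 16.1 (Ser2P), 4.05 to 11.8 and 4.44 to 12.2 (Ser5P) and 2.48 to 6.96 and 2.86 to 7.28 (Pol II).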

Other observations

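The tests in this part were all chosen after the results were seen. In KARPAS422, immediate-early genes lost CDK9 peaks: FOS, FOSB, EGR1 and DUSP1, transcription factors and a phosphatase induced within minutes of a stimulus, had a peak in both DMSO lists and in no treated list. These were 4 of the 9 members without a treated peak (44.4%, against 2.37% of other genes; Fisher's exact test, two-sided, odds ratio 32.9, adjusted p = 0.00530). In all, 126 genes were lost, while another split of the same 4 lists left 246 genes on one side, so loss alone does not exceed the spread between lists; the other splits held at most 1 immediate-early gene on a side that mixed the groups. A hypothesis is that CDK9 may leave these genes under CDK-TCIP1 in this line; the test was made on the data in which the losses were noticed. No list lost members past the threshold in SUDHL5, where 2 genes were lost with ab239364 and 0 with CST2316S.

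The strongest peak by q of all 4 ab239364 lists lay in KMT5B, a histone methyltransferase gene. With CST2316S in SUDHL5 it lay at the histone genes H2AC16 and H1-5 in both DMSO lists and in IRAG2 in both treated lists. These peaks were chosen after their values were seen.

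Of the 1959 regions gained with both antibodies in SUDHL5, 62.9% ± 6.71 held a Ser5P peak at 2 h and 53.3% ± 9.24 in DMSO (SD, n = 2 each; exact permutation, two-sided, p = 0.667). The lowest list at 2 h lay -1.74 percentage points from the highest DMSO list, within the spread of the lists, so whether Ser5P may follow CDK9 there cannot be told apart from the spread between lists.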
